A study of Mus musculus with 2 samples.

How the data were processed

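Total RNA was sequenced from gastrocnemius, the large calf muscle, of male B6CASTF1/J mice aged 2 months. These mice are first-generation hybrids of the laboratory strain B6 and the wild-derived strain CAST. The series holds 1 group of 2 libraries, numbered as biological replicates in the labels, each made from 300 ng of RNA with ERCC spike-in RNA added. The labels give each library its own tissue sample but the same donor entry, and do not state outright that the tissue came from separate animals. Differences between the libraries therefore measure the spread between these samples, part of which may be technical.

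Each library came with a gene table and a transcript table of one kind, called the first tables here, and with a transcript table of another kind, called the second tables. Per the file headers, the first tables hold expected counts, TPM, and the posterior mean and standard deviation of each count. Their layout is that of RSEM, and the notes deposited with each sample derive them from reads aligned to the transcriptome. The second tables hold estimated counts and TPM per transcript in the layout of kallisto, and the deposited notes derive each from 1 file of reads. The programs and their versions are not given in the sources used here. The deposited notes give the mm10 assembly and GENCODE annotation release M21 for all tables. The posterior standard deviation and the posterior mean TPM were read as scores deposited by the authors. For long transcripts, effective length was 99 nt below transcript length in the first tables, and 343 nt (replicate 1) or 338 nt (replicate 2) below it in the second tables. Short RNAs may therefore be counted differently by the 2 kinds of table, though this was not tested as the cause of their differing levels. Reads were assigned to a reference of the B6 type, so reads of CAST alleles can match less well, and the alleles were not separated. Whether the counting used strand is not given in the sources used here, so reads of a gene and of its antisense partner may be mixed.

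The first gene tables list 55536 genes, and all 55536 gene identifiers matched the GENCODE M21 annotation on the mm10 (GRCm38) assembly, from which symbols, biotypes and coordinates were taken. They also list 96 ERCC RNAs, 1 phiX174 sequence and 26248 entries with numeric identifiers. The numeric entries held 1 read in replicate 1 and 0 in replicate 2, and they name no gene, so they were left out of the tests. Where 2 genes share a symbol, values are those of the identifier with more reads, unless another identifier is given. The second tables were summed to genes.

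The expected counts deposited by the authors totalled 42925570 in replicate 1 and 42467674 in replicate 2, spike-ins included. A count of 0 allows up to 3 reads, or 0.0699 CPM in replicate 1 and 0.0706 CPM in replicate 2. Intervals on shares and on ratios are exact Clopper-Pearson intervals at 95%, and they cover counting error only, since reads are not independent molecules.

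Values of the group are given as mean ± SD over the 2 libraries (n = 2). With 1 group no edgeR quasi-likelihood test could be made, and the comparison between the libraries describes these libraries and has no replicate check. Ratios were coded as replicate 2 over replicate 1, on counts scaled by TMM factors from edgeR 4.0.16 in R 4.3.3, with 0.5 added to each count. Expected counts were rounded to whole numbers and each gene with a summed count of at least 20 was tested by an exact two-sided conditional binomial test, adjusted by the Benjamini-Hochberg method over all genes tested. Among all genes, a gene was called different at an adjusted p under 0.05 together with a fold of at least 2. Members of lists are called higher, or past the threshold, at an adjusted p under 0.05 alone, whatever their fold. Where a library had 0 reads, a lower bound of the fold was computed against 3 reads in that library. The biological coefficient of variation was the square root of the common dispersion of edgeR in a model with an intercept alone. Correlations across genes used log2(TPM + 1), and those across spike-in RNAs log2(TPM + 0.01). Genes are not independent replicates, so these correlations carry no p.

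Before the data were examined, 36 gene lists with 528 entries, 11 pairs of fast and slow muscle isoforms, 30 genes with known alternative transcripts, the tests, the alternatives and the rule for naming genes were fixed. The median log2 ratio of each list with at least 5 members tested was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Named genes are the 20 with the highest mean TPM, the 3 most abundant members of each list, all Y-linked and X-inactivation genes and fast and slow pairs, and the 10 genes with the largest fold each way among those with a summed count of at least 200 that passed the test. They further include the 4 members farthest in the direction of the median in each list outside the central 95% of its random lists, and the isoform genes whose top transcript differed or whose mean TPM was among the 5 highest. Other names were chosen after their values were seen, among them Rpl21, Ucp3, Col1a2, Ldhb, Dgat2, Bdh1, Idh2, Plin5, Ppara, Mb, Esrrg, Ppargc1a, C3, Col14a1, Egr1 and Zfp36. The list of genes taken as STAT3 targets, and Socs2, were chosen after Cish and Socs3 were seen and before their own values were. Some genes that the rule names are not reported. Copies were found with BLAST 2.17.0 against all annotated transcripts. Alternatives covered the scaling (total counts, DESeq2 1.42.0 size factors, ERCC), the count minimum, the pseudocount, the fold, the kind of table, and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

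The calculations were tested on simulated data. In libraries drawn with counting noise alone, 200 genes were changed and 14806 were tested. The binomial test at an adjusted p under 0.05 recovered 67.2% of 64 genes changed by 1.5-fold, 74.6% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, and called 7 unchanged genes. In libraries drawn with a coefficient of variation of 0.15 and no changed gene, the estimate was 0.149 over 14816 genes. There the test called 5707 unchanged genes, 129 of them with a fold of at least 2. In that simulation, where genes vary independently, 5.0% of 200 unshifted lists of 15 genes lay outside the central 95%, and 99.5% of lists shifted by 0.5 on the log2 scale lay above it.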

Results

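The data describe steady-state RNA of adult mouse gastrocnemius, a mixed calf muscle made mostly of fast fibres. The group comprised 2 libraries of total RNA from male B6CASTF1/J mice aged 2 months, called replicate 1 and replicate 2. Expected counts summed over genes came to 42724520 in replicate 1 and 42280091 in replicate 2. With 1 group, no comparison between conditions is implied by the design. The questions addressed are what the muscle expressed, and by how much the libraries differed.

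Y-linked transcripts were present in both libraries, and the labels give both as male. Ddx3y was at 26.1 ± 1.24 TPM (SD, n = 2), Eif2s3y at 10.8 TPM in replicate 1 and 19.3 TPM in replicate 2, Uty at 6.45 ± 0.127 and Kdm5d at 4.17 ± 0.113 TPM. Sry, Zfy1 and Usp9y had 0 reads in both libraries, which allows up to 3 reads in each. Xist, the RNA that coats the inactive X chromosome, was at 0 TPM in replicate 1 and 0.01 TPM in replicate 2, and Tsix was at 0 in both.

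In both libraries 10731 genes reached a TPM of 1, 9824 of them protein coding. The libraries alone held 11148 and 11068 such genes. Muscle contraction and energy genes led the protein-coding RNA. The skeletal actin gene Acta1 was at 17570 ± 1306 TPM, and Ckm, the muscle creatine kinase, at 16782 ± 2722. Fast troponin T (Tnnt3) reached 13398 ± 2133, the fast regulatory light chain Mylpf 11374 ± 2229, aldolase A (Aldoa) 9983 ± 1864, Tpm1 9704 ± 1835, the fast calcium pump Atp2a1 9600 ± 1113 and Myl1 8355 ± 1860 TPM. Titin (Ttn) was at 2664 ± 217 TPM and Myh4, the fastest myosin heavy chain, at 9849 ± 2005 TPM.

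Structural and ribosomal RNAs took a large part of TPM in this total RNA. Rn7s1 and Rn7s2, which encode the 7SL RNA of the signal recognition particle, were each at 144895 ± 8039 TPM. Their transcripts are 100% identical over 300 nt, so the equal values are a split of shared reads. Rn7sk was at 13164 ± 698 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 were at 73132 ± 15399 and 47377 ± 9478 TPM. Rn7s1, Rn7s2 and Rn7sk were at 0 TPM in replicate 1 of the second tables, and genes of up to 300 nt held 34.4% of TPM in the first tables of that library and 0.027% in the second. Levels of such short RNAs thus hold for the first tables alone. Levels of longer genes also depended on the kind of table, which the SD over the 2 libraries does not include. Acta1 was at 41778 TPM (replicate 1) and 35554 TPM (replicate 2) in the second tables, against 18494 and 16647 in the first. Protein-coding genes held 46.7 ± 0.708% of TPM and 77.7 ± 2.49% of expected counts in the first tables. They held 76.5% (replicate 1) and 71.8% (replicate 2) of TPM in the second. The class with the 7SL genes held 30.3 ± 1.69% of TPM and 4.93 ± 0.233% of counts. The 20 most abundant genes held 60.7 ± 0.0906% of TPM, and the 100 most abundant 75.7 ± 0.346%.

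Mitochondrial mRNAs were abundant, with mt-Co1 at 15858 ± 2880 TPM, mt-Cytb at 8946 ± 694 and mt-Nd1 at 7644 ± 698. The 13 mitochondrial mRNA genes held 4.68% of expected counts in replicate 1 and 5.73% in replicate 2, and all 37 mitochondrial genes 14.9% and 19.6%. Part of this RNA was counted on nuclear copies on chromosome 1. Gm28661 (24614885 to 24615565, mm10) is 100% identical to mt-Co2 over 681 nt and stood at 16239 ± 1911 TPM, against 97.2 TPM (replicate 1) and 194 TPM (replicate 2) for mt-Co2. Gm10925 is 100% identical to mt-Atp6 over 678 nt and was at 14529 ± 777 TPM, and Gm28437 is 100% identical to mt-Co3 over 783 nt and was at 12574 ± 681 TPM. Gm29216 is 99.8% identical to mt-Co1 over 483 nt and was at 8372 ± 1117 TPM. With these 4 copies added, the share of counts was 6.92% in replicate 1 and 8.28% in replicate 2.

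Myh4 dominated the adult myosin heavy chains. Its share of the summed TPM of Myh4, Myh1, Myh2 and Myh7 was 89.9% in replicate 1 and 76.8% in replicate 2, a mean of 83.3 ± 9.31% (SD, n = 2). Myh1 held 7.19 ± 3.69%, Myh2 6.25 ± 3.36% and Myh7, the slow myosin heavy chain, 3.22 ± 2.26%. Myh4 (67238029 to 67260446), Myh1 and Myh2 lie on chromosome 11 and Myh7 (54970684 to 54994626) on chromosome 14 of mm10. In the second tables Myh4 held 87.3% and 72.9%, and Myh1 7.75% and 15.9%.

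**Figure D1:**
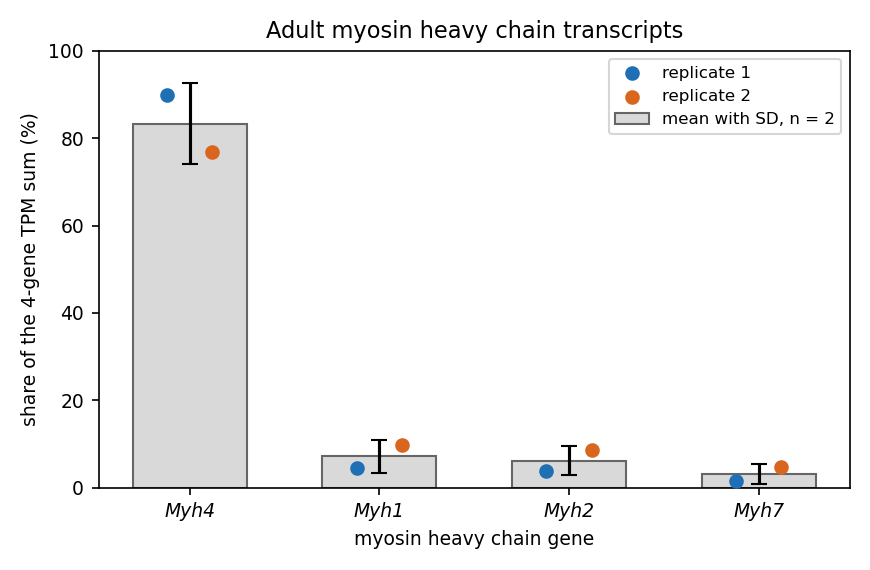
Share of each adult myosin heavy chain gene in the TPM sum of all 4 (%), with bars for the mean, error bars for the SD (n = 2) and a point per library. Myh4 held 89.9% in replicate 1 and 76.8% in replicate 2, and the other genes were higher in replicate 2.

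Fast isoforms exceeded slow isoforms in all 11 pairs and in both libraries (exact two-sided sign test over the pairs, p = 0.000977). The pairs are genes of the same muscle, not animals, and may vary together, so this p does not measure the spread between animals. The fast over slow ratio was largest for calsequestrin, Casq1 over Casq2, at a log2 ratio of 6.56 ± 1.12 (SD, n = 2). It was 5.91 ± 1.22 for Tnni2 over Tnni1, 5.77 ± 1.14 for Tnnt3 over Tnnt1, 5.38 ± 1.02 for Atp2a1 over Atp2a2 and 5.28 ± 1.07 for Tpm1 over Tpm3. The 3 fast myosins over Myh7 gave 5.11 ± 1.14, Tnnc2 over Tnnc1 4.72 ± 1.12, Myl1 over Myl3 4.62 ± 1.31 and Mylpf over Myl2 4.51 ± 1.27. The smallest ratios were 3.04 ± 0.99 for Actn3 over Actn2 and 2.09 ± 0.90 for Mybpc2 over Mybpc1. Actn2 also stands in the list of sarcomere genes shared by all fibres, so that pair compares a fast form with a shared form. Every pair had a lower ratio in replicate 2, with a median difference of -1.59 on the log2 scale.

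**Figure D2:**
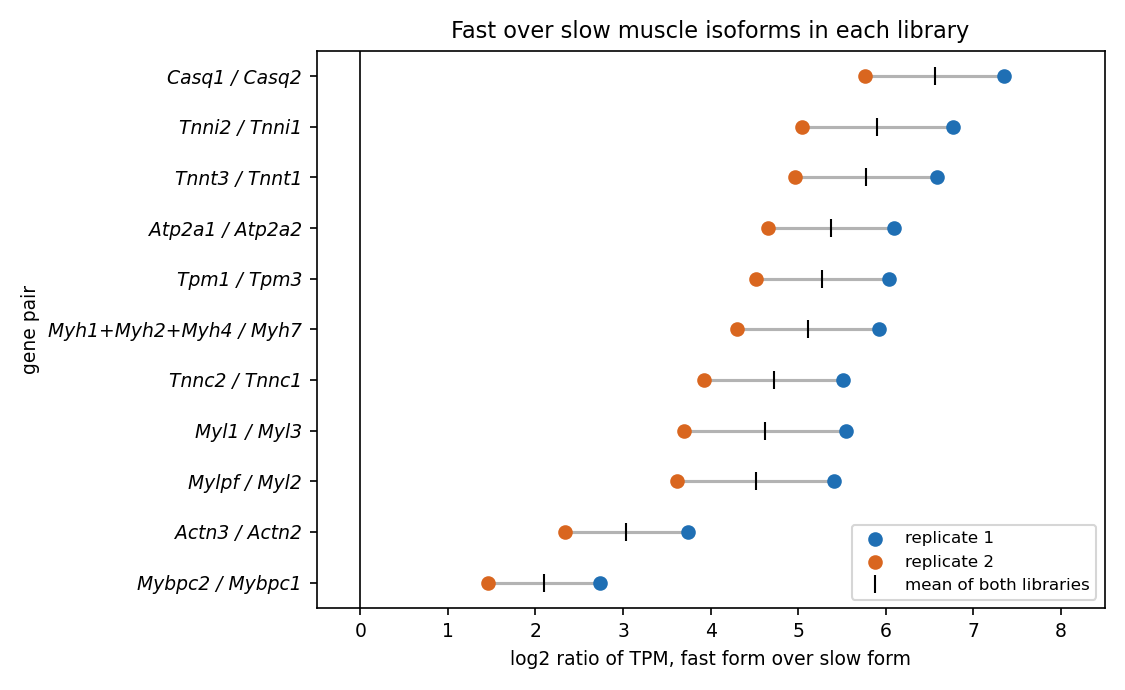
Log2 ratio of TPM of the fast form over the slow form for 11 gene pairs, with a point per library and a tick at the mean. All pairs lie above 0, and the replicate 2 point lies left of the replicate 1 point in each.

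Glycolytic and contractile RNA far exceeded RNA of lipid use. The fast-fibre list of 15 genes summed to 89490 ± 15060 TPM and the slow-fibre list to 3105 ± 1758 TPM, led by Myl2 (552 ± 350), Mybpc1 (387 ± 132) and Myl3 (375 ± 237). Sarcomere genes shared by all fibres, 19 of 20 found in the annotation, summed to 52070 ± 2617 TPM. The glycolysis and glycogen list summed to 28120 ± 4162 TPM, led by Aldoa, Gapdh (4291 ± 526) and glycogen phosphorylase Pygm (3527 ± 573). In the second tables this list summed to 47020 ± 8518 TPM, with Gapdh at 14540 TPM in replicate 1 and 11460 in replicate 2. Nuclear genes of oxidative phosphorylation summed to 10820 ± 1603 TPM, led by Atp5b (1430 ± 235), Slc25a4 (1135 ± 88.3) and Cox8b (871 ± 93.1), and fatty acid oxidation genes to 2370 ± 1081 TPM, led by Fabp3 (440 ± 317), Pdk4 (250 ± 85.1) and Lpl (233 ± 154). Genes that couple excitation to contraction summed to 4004 TPM in replicate 1 and 3519 TPM in replicate 2, among them the calcium release channel Ryr1 (767 ± 67.0), Trdn (498 ± 77.1) and Srl (455 ± 36.1). Among myogenic regulators, Nfix was at 182 ± 0.403 TPM, Mef2c at 137 ± 2.76 and Tead1 at 80.0 ± 8.43. Genes of the developmental list stayed low, with Myh8 at 98.6 ± 19.4 TPM, Actc1 at 75.5 ± 38.1 and the heart myosin gene Myh6 at 73.7 ± 44.1. In the second tables Myh6 was lower, at 22.5 TPM in replicate 1 and 57.1 in replicate 2, while Myh8 and Actc1 were higher. Neuromuscular junction genes summed to 88.7 ± 5.77 TPM, led by Musk (23.1 ± 4.26), Dok7 (11.1 ± 2.03) and Rapsn (10.4 ± 0.940).

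Genes listed as markers of other cell types were present at lower levels. Muscle fibres can express some of them, such as Des, so the sums do not show how much RNA came from those cells. Fibro-adipogenic genes summed to 580 ± 109 TPM, with Gsn at 201 ± 90.8, Dcn at 96.9 ± 13.5 and Col1a1 at 74.3 ± 19.4. Endothelial genes summed to 212 ± 8.59 TPM, led by Fabp4 (60.4 ± 7.59), Ly6c1 (52.8 ± 0.615) and Egfl7 (21.04 in replicate 1 and 14.95 in replicate 2), and mural cell genes to 182 ± 17.5, led by Rgs5 (56.6 in replicate 1 and 59.4 in replicate 2), Abcc9 (50.3 ± 3.97) and Acta2 (17.0 ± 5.24). Erythroid genes summed to 227 ± 15.2 TPM, with the globins Hbb-bs at 81.2 ± 1.75, Hba-a1 at 79.3 ± 9.36 and Hba-a2 at 57.4 ± 3.42. The adipocyte list summed to 129 ± 7.59 TPM, of which Plin4 made 106 ± 6.44, Acaca 6.51 ± 0.940 and Lipe 5.75 ± 0.679. The median of that list was 0.36 TPM in replicate 1 and 0.21 in replicate 2, and 6 of 14 members reached a TPM of 1. The sum thus mostly reflects Plin4 and does not show how much RNA came from adipocytes. Tendon genes summed to 83.4 ± 28.7 TPM, led by Fmod (29.6 ± 12.1), Thbs4 (28.3 ± 6.51) and Chad (5.79 ± 2.90). Schwann cell genes summed to 35.8 ± 3.68 TPM, with Pmp22 at 11.0 ± 0.410 and Mbp at 8.55 ± 1.66, and macrophage genes to 31.5 ± 4.23, led by Lyz2 (11.6 ± 0.516), C1qb (2.93 ± 0.523) and Csf1r (2.76 ± 0.933). In the satellite cell list, Des, which muscle fibres also express, was at 846 ± 22.2 TPM, Itga7 at 21.6 ± 1.85 and Sdc4 at 16.7 ± 1.51, while 8 of 14 members reached a TPM of 1. Genes of cell division were low, with Pcna at 7.33 ± 0.163 TPM, Mcm2 at 2.04 ± 0.785 and Mcm3 at 1.00 ± 0.219, and 2 of 15 members reached a TPM of 1.

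The libraries were close in rank and far apart beyond counting noise. Across 23309 genes above 0 TPM in either library, Pearson r of log2(TPM + 1) was 0.992 and Spearman rho 0.945. A chi-square test of the counts of 14817 genes gave 71.6 per degree of freedom, so the 2 libraries are not copies of 1 library. The same statistic was 1.38 over 43 ERCC RNAs. Among genes with a summed count of at least 200, the log2 ratio had an SD of 0.338 over 10054 genes, against 0.0975 over 27 ERCC RNAs, and 94.6% of the genes lay within 1.5-fold. ERCC RNAs took 0.468% of expected counts in replicate 1 (95% interval 0.466 to 0.470) and 0.442% in replicate 2 (0.440 to 0.444). The biological coefficient of variation was 0.1498. These correlations and ratios are across genes, which are not independent replicates.

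**Figure D3:**
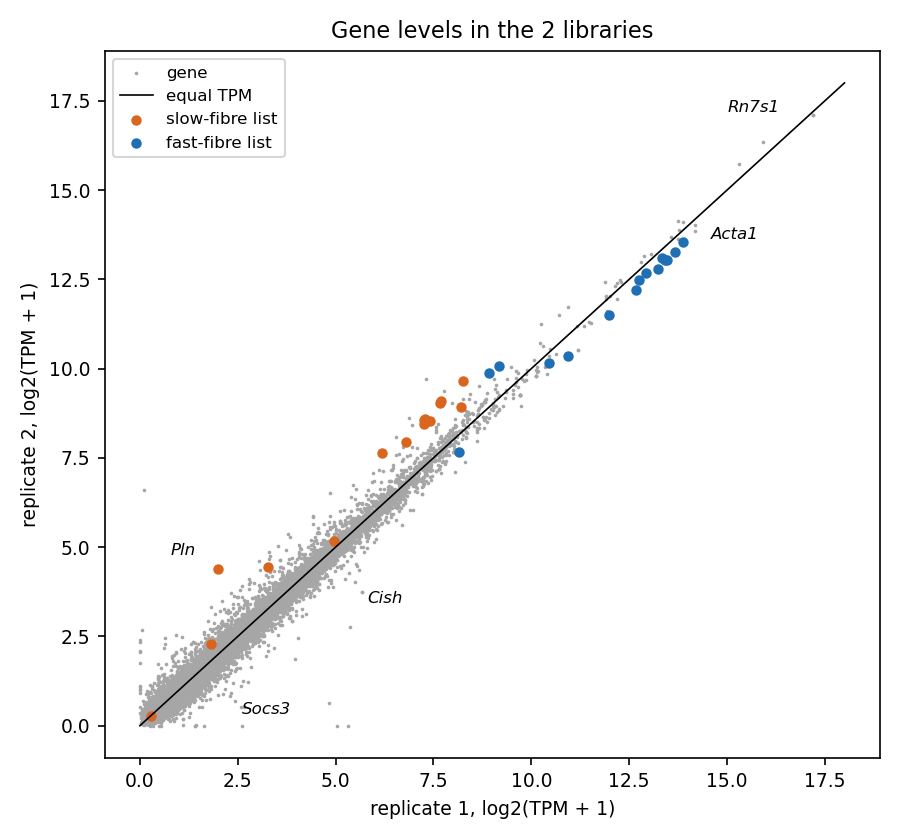
Gene levels in replicate 1 (x axis) and replicate 2 (y axis) as log2(TPM + 1), with a point per gene with a summed count of at least 20 and a line of equal TPM. Most members of the slow-fibre list lie above the line, most members of the fast-fibre list just below it, and Socs3 and Cish far below it.

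Slow-fibre and oxidative genes were higher in replicate 2. All 14 slow-fibre genes tested were higher there, 11 of them by at least 2-fold, with a median log2 ratio of 1.33 (2.51-fold), above the range of random lists (-0.12 to 0.15). Phospholamban (Pln), which restrains the slow calcium pump, had a log2 ratio of 2.36 (95% interval 2.12 to 2.61), Tnni1 1.51 (1.44 to 1.57), Myl2 1.45 (1.40 to 1.49) and Myl3 1.44 (1.39 to 1.48). Of 18 fatty acid oxidation genes 17 were higher in replicate 2 and 1, Ucp3, was higher in replicate 1, with a median of 0.83. Fabp3, the heart-type fatty acid carrier, had 1.67, lipoprotein lipase (Lpl) 1.53, Ech1 1.07 and the fatty acid transporter Cd36 1.07. All 22 oxidative phosphorylation genes were higher in replicate 2, with a median of 0.35, led by Sdhb at 0.71, Cox6a2 at 0.51, Uqcrfs1 at 0.51 and Atp5g1 at 0.50. All 13 mitochondrial mRNAs were higher in replicate 2, with a median of 0.25. The farthest in the first tables were mt-Co2 at 1.04, mt-Co3 at 0.83, mt-Nd6 at 0.60 and mt-Atp6 at 0.59. In the second tables the farthest were mt-Nd3 at 1.38 (0.08 in the first) and mt-Nd4l at 0.80, with mt-Co2 at 0.42. There mt-Atp8 was at 0 TPM in both libraries. Summed with their nuclear copies, mt-Co2, mt-Co3 and mt-Atp6 gave 0.29, 0.27 and 0.26. Adjusted over the list alone, 14 slow-fibre, 18 fatty acid oxidation, 22 oxidative phosphorylation and 13 mitochondrial mRNA genes passed, as many as over all genes.

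Fast-fibre and glycolytic genes were higher in replicate 1. Of 15 fast-fibre genes 13 were higher in replicate 1, with a median log2 ratio of -0.34, led by Mybpc2 at -0.52, Actn3 at -0.45, Mylk2 at -0.45 and parvalbumin (Pvalb) at -0.42. The other 2, Myh1 and Myh2, encode the IIx and IIa myosins and were higher in replicate 2, at 0.94 and 1.02. Of 20 glycolysis and glycogen genes 15 were higher in replicate 1 and 2 in replicate 2, with a median of -0.20, led by the phosphorylase kinase subunits Phka1 at -0.44 and Phkg1 at -0.41, then Gpd1 at -0.38 and Pgm1 at -0.33. Of 17 excitation-contraction genes 15 were higher in replicate 1, with a median of -0.13, led by Cacng1 at -0.39, Trdn at -0.25, Jph1 at -0.22 and Bin1 at -0.18. Sarcomere genes shared by all fibres went both ways, 12 higher in replicate 1 and 6 in replicate 2, with a median of -0.07 inside the random range. Acta1 had -0.10 and Ckm -0.29. Adjusted over the list alone, 15 fast-fibre, 18 glycolysis, 17 excitation-contraction and 18 sarcomere genes passed.

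Tendon and connective tissue genes moved apart. Of 12 tendon genes 10 were higher in replicate 2, with a median of 0.83, led by Cilp2 at 1.20, Chad at 1.11, Comp at 1.08 and Col11a1 at 1.02. Of 15 fibro-adipogenic genes 11 were higher in replicate 1 and 2, Col1a1 and Col1a2, in replicate 2, with a median of -0.39. Pi16, a marker of universal fibroblasts, was 2.30-fold higher in replicate 1, and log2 ratios were -0.91 for Gsn, -0.89 for Dpt and -0.79 for Clec3b. The heat-shock list had a median of 0.34, with 6 of 13 genes higher in replicate 2 and 3 in replicate 1, led by Cryab at 0.85, Hspb7 at 0.81, Hspb6 at 0.80 and Hspe1 at 0.45. Endothelial genes had a median of 0.15, with 7 of 14 higher in replicate 2 and 1 in replicate 1, led by Emcn at 0.69, Kdr at 0.47, Flt1 at 0.32 and Fabp4 at 0.28. The mean of this list lay inside the random range. Hspa8 was at 484 ± 34.9 TPM, Cryab at 483 ± 193 and Hspb6 at 456 ± 164. Adjusted over the list alone, 10 tendon, 13 fibro-adipogenic, 10 heat-shock, 8 endothelial and 5 developmental genes passed. In the developmental list Tnnt2 had 1.78, Myh6 1.36 and Myh3 0.51, all at an adjusted p under 0.05 and the first 2 also past 2-fold, and Chrnd 0.46 (adjusted p = 0.165). Actc1, at -1.03, and Myh8 were higher in replicate 1, and the list median of 0.43 was 0.21, inside the random range, at a summed count of at least 200.

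Some list medians outside the random range rested on members that did not pass the test alone. The interferon list had a median of 0.31, but 1 of 12 members passed the threshold. Ifit3 at 0.81, Rtp4 at 0.69, Rsad2 at 0.68 and Bst2 at 0.67 did not. The adipocyte list had a median of -0.40, with 4 of 10 members higher in replicate 1 and 2 in replicate 2. Adipoq at -1.11, Cidec at -0.86 and Plin1 at -0.85 did not pass, and Cfd at -0.83 did (adjusted p = 0.000283). Nuclear long noncoding RNAs had a median of -0.29, with 4 of 9 higher in replicate 1, among them Malat1 at -0.32 and Meg3 at -0.40, while Mirg at -1.12 and Rian at -0.30 did not pass. In all, 15 of 32 lists lay outside the central 95% of their random lists, 9 higher in replicate 2 and 6 in replicate 1. Random lists ignore that members of a list vary together and that lists share genes, so the number that unchanged samples would give is not known. Means of the interferon, adipocyte and nuclear noncoding lists lay inside their random range. Adjusted over the list alone, 1 interferon, 6 adipocyte and 4 nuclear noncoding genes passed. Ifi27 was at 19.2 ± 1.17 TPM, Bst2 at a mean of 2.14, Malat1 at 1277 ± 209, Neat1 at 190 ± 42.7 and Meg3 at 5.97 ± 0.495 TPM.

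The medians of the other 17 lists lay inside their random range, and 4 lists had too few members to compare. Medians were 0.10 for the neuromuscular junction, 0.08 for satellite cells, 0.06 for ribosomal proteins, 0.01 for histones and 0.01 for cell division. They were -0.01 for myogenic regulators, -0.02 for glucocorticoid and fasting genes, -0.02 for circadian genes, -0.02 for immediate-early genes and -0.02 for mural cells. Macrophage genes had -0.05, atrophy genes -0.06, small structured RNAs -0.06, erythroid genes -0.10, imprinted genes -0.11 and Schwann cell genes -0.16. Outside the random range were the macrophage median at a summed count of at least 200 (-0.43), the imprinted median in the second tables (-0.16), and the means of the imprinted (-0.21) and atrophy lists (-0.15). Of 21 ribosomal protein genes 7 were higher in replicate 2, and 9 passed adjusted over the list alone. Of 16 immediate-early genes 2 were higher in replicate 2 and 4 in replicate 1, and 6 passed adjusted over the list alone. Of 17 circadian genes 2 were higher in replicate 2 and 5 in replicate 1, and 7 passed adjusted over the list alone. Tef at -0.12 and Nr1d1 at -0.11 passed, and Dbp at 0.08 did not. Trim63, an atrophy ligase, was at 95.2 ± 4.24 TPM, Fbxo32 at 69.0 ± 8.61 and Fbxo31 at 55.7 ± 0.622. Nr4a1 was at 51.4 ± 6.40 TPM, Tsc22d3 at 93.5 ± 2.77, Sgk1 at 86.0 ± 6.31, Dusp1 at 28.6 ± 0.0141 and Jun at 18.3 ± 3.05 TPM. H19 was at 190 TPM in replicate 1 and 328 TPM in replicate 2, Snrpn at 23.3 and 26.6 TPM, and Igf2r at 14.7 ± 0.403 TPM. Rplp1 was at 518 ± 0.834 TPM, Rpl3l at 296 ± 1.78, Rplp0 at 233 ± 15.4, H3f3a at 123 ± 0.0354, Hist1h1c at 56.1 ± 4.69 and Hist1h4h at 54.6 ± 4.59 TPM. Mean and median differed in sign for the sarcomere list (mean 0.11), small structured RNAs (0.03), glucocorticoid and fasting genes (0.14), myogenic regulators (0.04) and cell division (-0.09).

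**Figure D4:**
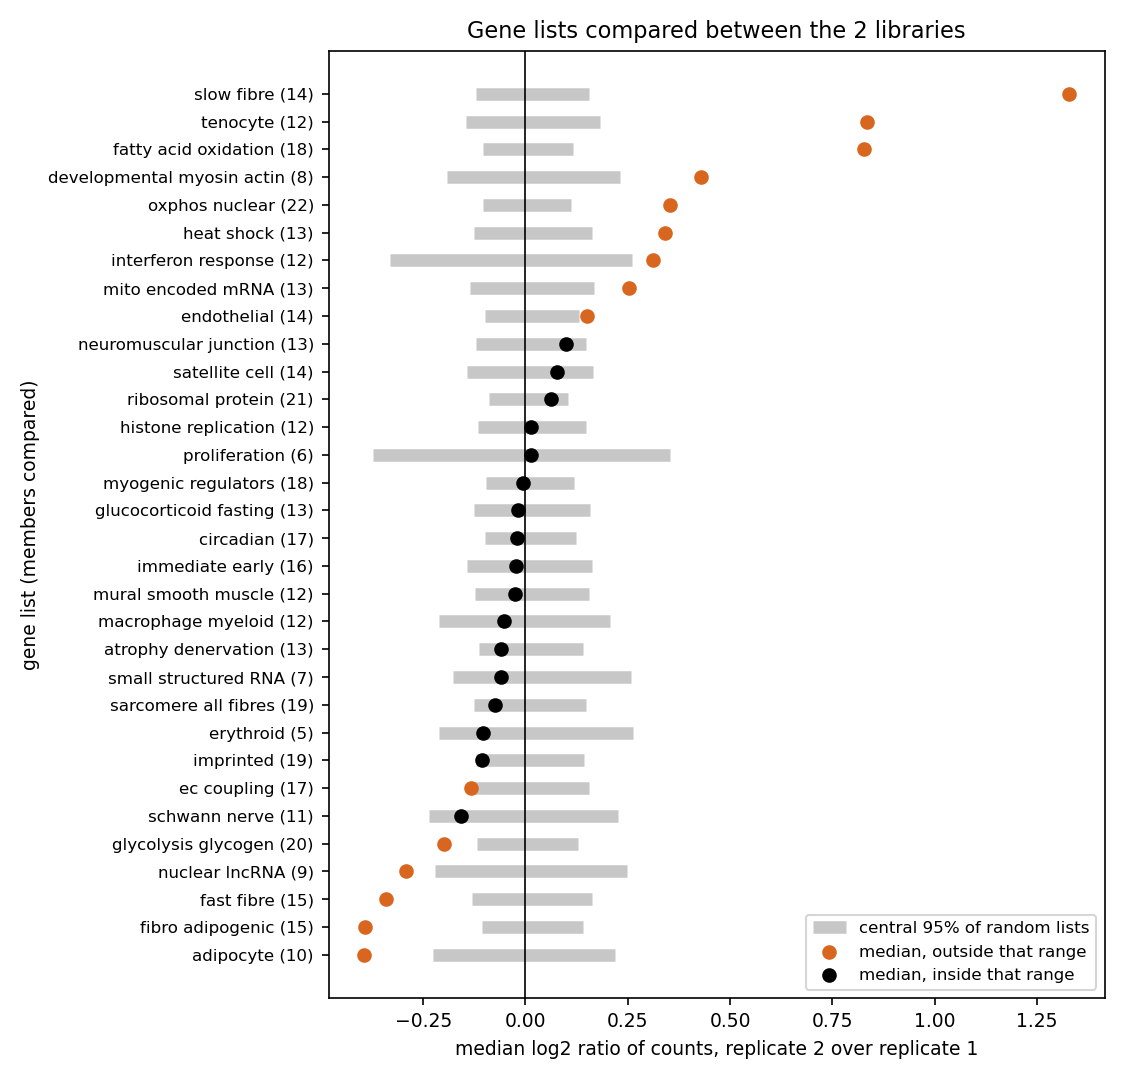
Median log2 ratio of counts, replicate 2 over replicate 1, for 32 gene lists, with the number of members compared and grey bars for the central 95% of 10000 random lists matched on expression. The slow-fibre list stands at 1.33 and the fast-fibre list at -0.34.

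By single gene, 3826 of 14817 genes differed between the libraries at an adjusted p under 0.05 (exact binomial test), and 455 of them by at least 2-fold, 269 higher in replicate 2 and 186 in replicate 1. Simulated libraries with a coefficient of variation of 0.15 and no changed gene gave 129 such genes. At an adjusted p under 0.05 alone they gave 5707, more than the 3826 observed. That setting is close to the 0.1498 estimated from these libraries, which includes their differences, and it was the same for every gene. The simulated numbers thus do not show how many genes unchanged samples would give. Wnt16 (chromosome 6, 22288227 to 22298522) had 31 reads in replicate 1 and 211 in replicate 2, a log2 ratio of 2.79 (2.26 to 3.41). Padi3 had 2.24, Cyfip2 1.86, Lrrc52 1.86, Dach2 1.79 and the noncoding AC132253.9 1.95. Higher in replicate 1 were Socs3 (chromosome 11, 117966079 to 117970047) at -2.39 (-2.82 to -2.00), a feedback inhibitor of cytokine signalling, and Cish (chromosome 9, 107296026 to 107302784) at -1.80 (-1.93 to -1.67), a feedback inhibitor of STAT5 signalling. Complement C7 had -1.97 and the antisense transcript Gm13091 -2.39. With at least 200 summed reads, 153 genes differed by 2-fold, 122 (79.7%) of them higher in replicate 2, against 59.1% among the 455. The genes named here kept their direction and a fold of at least 2 in the second tables. With 1 library each, this test compares libraries and has no replicate check.

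Several of the largest ratios in the first tables were not found in the second. The 1700047I17Rik2 gene had 276 reads in replicate 1 and 0 in replicate 2, and 0 reads in both second tables. Set against 3 reads, it was at least 89.0-fold higher in replicate 1, a bound that covers counting error only. Its relative posterior SD was 6705%, the larger of the 2 libraries with counts under 1 taken as 1. Read assignment could therefore make the fold smaller. Gm14288 had a log2 ratio of -3.52 in the first tables and 0.13 in the second, Gm12070 -2.75 and -0.30, and the small nuclear RNA gene Gm24497 2.44 with 0 reads in the second tables. Gm14440 had expected counts of 3.27 and 610 in the first tables and 0 and 0.9 in the second, where its ratio of over 2-fold rests on those 0.9 reads. The processed pseudogene Gm10163 (chromosome 9, 88390837 to 88391317) kept its direction in the second tables, with expected counts of 1.06 and 1269 in the first and 0 and 225.5 in the second, and those of Gm10240 and Gm13370 were each 659 and 163 in the first. Nnt, which encodes a mitochondrial transhydrogenase, has 2 identifiers at nearly the same place on chromosome 13. ENSMUSG00000025453 had a log2 ratio of 1.59 and ENSMUSG00000116207 one of -3.44 in the first tables, against 1.88 and 1.00 in the second. First-table counts in replicates 1 and 2 were 2174 and 6335 for ENSMUSG00000025453, and 555 and 49 for ENSMUSG00000116207. The relative posterior SD of ENSMUSG00000116207 was 804%, so its ratio of -3.44 could come from read assignment between the identifiers. In each kind of table, the Nnt identifier with more reads was higher in replicate 2.

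Transcripts were less certain than genes. Between the first and second tables, Pearson r of log2(TPM + 1) was 0.734 (replicate 1) and 0.742 (replicate 2) across transcripts, 0.929 and 0.933 across genes, and 0.984 and 0.985 across protein-coding genes. Of 30 genes with known alternative transcripts, 28 had the same top transcript in both libraries of the first tables, and 21 had it in all 4 tables. The exceptions between libraries in the first tables were Tnnt3, with Tnnt3-224 at 48.2% of its TPM in replicate 1 and Tnnt3-201 at 42.9% in replicate 2, and Nfix, with Nfix-204 at 40.6% and Nfix-201 at 40.2%. In the second tables Nfix-204 led in both libraries, at 46.6% and 47.7%. Tnnt3 differed there too, but with Tnnt3-218 and Tnnt3-225 on top, and so did Mbnl1, with Mbnl1-201 and Mbnl1-210. These changes thus depend on the kind of table. Top transcripts also differed between tables for Myl1, Pkm, Ndrg2, Tnnt1, Mbnl1, Capzb and Mylk. In the first tables Tpm1-205 made 97.1 ± 0.276% of Tpm1, Atp2a1-201 99.8 ± 0.0495% of Atp2a1, Myl1-202 73.7 ± 0.849% of Myl1 and Tpm2-202 45.9 ± 0.516% of Tpm2. The SD over the libraries does not include the difference between tables. In the second tables Tpm1-205 made 75.6% (replicate 1) and 75.9% (replicate 2), Atp2a1-201 99.9% in both and Tpm2-202 53.2% and 56.0%. There Myl1-207 led Myl1, at 38.4% and 36.1%.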

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

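No test in this part was chosen after its result was seen. The deposited identifier of phiX174, a bacteriophage, names it as a spike-in, so its reads lie outside the measurement of muscle RNA. The replicate 1 library had 5 such reads and replicate 2 had 3, too few to tell the libraries apart. No biological explanation was tested.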

How the results depend on the processing

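All alternatives were set before the data were examined, except 4 chosen after seeing the data, which asked for a 2-fold ratio in both kinds of table, restricted the top 20 share or the detected genes to nuclear protein-coding genes, or added the nuclear copies to the mitochondrial share. Where a value moved, the cause was not tested unless the construction shows it. Genes that differed by 2-fold numbered 455, and 451 to 465 under 3 other scalings. The split, higher in replicate 2 against replicate 1, was 269 to 186, and shifted to 251 to 200 with total counts and 306 to 159 with ERCC scaling. There were 495 with no minimum, 369 with counts deflated by their posterior spread and 316 in both kinds of table. With fewer genes tested, at a summed count of at least 200, there were 153, and with a 1.5-fold limit 1007. Detected genes fell to 6333 at a TPM of at least 5. The correlation was 0.98 with a pseudocount of 0.1, and the coefficient of variation 0.138 at a summed count of at least 200. The top 20 genes held 59.8% of TPM without mitochondrial genes, 47.5% of counts, 50.9% in the second tables and 37.3% among nuclear protein-coding genes. The 13 mitochondrial mRNAs held 6.90% by TPM, and 7.60% of counts with their copies. Spike-in RNA held 0.734% by TPM and 0.336% in the second tables. Protein-coding genes held 77.7% of counts, and 49.1% of TPM without mitochondrial genes. Leaving out mitochondrial genes, here and for the top 20, kept their nuclear copies, on which part of the mitochondrial RNA was counted. Leaving out each library returns the value of the other alone, so the ranges repeat values per library and are no separate check. They were 11068 to 11148 detected genes, 60.6 to 60.7% for the top 20, 76.8 to 89.9% for Myh4 and 11 to 11 isoform pairs. Further ranges were 394 to 397 list members at a TPM of 1, 4.68 to 5.73% for mitochondrial mRNAs, 0.442 to 0.468% for spike-ins and 46.2 to 47.2% for protein-coding genes. The fast isoform was higher in all 11 pairs with expected counts, in the second tables and with a pseudocount of 1. The lists outside their random range numbered 13 to 15. The developmental median moved inside it at a summed count of at least 200 (0.21), as did the adipocyte median (-0.16), and the interferon (0.24) and nuclear noncoding (-0.22) medians in the second tables. Means of the endothelial, adipocyte, interferon and nuclear noncoding lists also lay inside. The macrophage median moved outside it at a summed count of at least 200 (-0.43) and the imprinted median in the second tables (-0.16), as did the means of the imprinted and atrophy lists. Some medians near 0 changed sign, among them macrophage (0.01) and immediate-early genes (0.02) in the second tables and myogenic regulators (0.05) under ERCC scaling. Sums of TPM moved by more than their SD for 35 lists in the second tables. Mean sums there were higher for the fast-fibre list (140200 against 89490 TPM) and the slow-fibre list (5463 against 3105). They were lower for small structured RNAs (5647 against 310900) and nuclear noncoding RNAs (1092 against 1483). No paired analysis was possible because the series holds 1 group. The agreement of top transcripts needs both libraries and was not run with either left out. Depth limits genes such as Adipoq and Ifit3, whose ratios did not pass the test.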

Other observations

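The tests of library scaling, of shared reads and of fibre composition for the slow-fibre genes, and of a stress response for Cish and Socs3, were chosen after the result was seen. Ighm, the immunoglobulin heavy constant mu gene, was at 54.3 ± 15.6 TPM (SD, n = 2), with 3530 and 2353 reads, while other lymphocyte genes were near 0, among them Cd79b at 0.16 TPM and Igkc at 0.135 TPM. The neuronal enzyme gene Gad1 had 111 reads in replicate 1 and 2 in replicate 2, a log2 ratio of -5.43 (95% interval -8.81 to -3.86), and -5.09 in the second tables. Other genes of the list of liver, kidney and neuron markers were near 0 (Slc17a7 at 0.11 TPM), except Myh6 at 73.7 ± 44.1 TPM in the first tables. Myh6 is a heart myosin gene that neighbours Myh7. Eif2s3y had a log2 ratio of 0.82 between the libraries, while Ddx3y had -0.01, Uty 0.12 and Kdm5d 0.15, none of these past the threshold.

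The genes in this paragraph were named after their values were seen, and each passed the test. Mb belongs to the sarcomere list and Esrrg and Ppargc1a to the myogenic regulators, whose medians were -0.07 and -0.01. Lactate dehydrogenase B (Ldhb) had a log2 ratio of 1.73, replicate 2 over replicate 1, Dgat2 1.72, Bdh1 1.68, Idh2 1.62, Plin5 1.58 and the nuclear receptor Ppara 1.38. Myoglobin (Mb) had 1.06, Esrrg 1.09 and Ppargc1a 0.69. Complement C3 had -1.07 and Col14a1 -1.04.

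Slow-fibre genes were higher in replicate 2, with a median log2 ratio of 1.33. The smallest median over 4 scalings was 1.30 and the median in the second tables was 1.32, which argues against library scaling and against the assignment of shared reads as the whole cause. The median lay at percentile 100 of random lists matched on expression and gene length, which argues against a trend with transcript length, as RNA degradation could give. The fast-fibre median was -0.34, but the fast genes Myh1 (0.94) and Myh2 (1.02) went with the slow genes. The slow genes ranged from 0.24 for Csrp3 to 2.36 for Pln, so 1 common factor for each of the 2 lists does not describe them all. The fast list pools genes of different fast fibre types, with Myh4 at -0.37 against the IIx and IIa myosins Myh1 and Myh2. This misfit therefore does not argue against a difference in fibre composition. Whether the muscles differed in fibre composition or the pieces came from different regions cannot be told apart, since each came as 1 library.

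Cish and Socs3 were higher in replicate 1, which may reflect cytokine or hormone signalling. For growth hormone acting through STAT5, a further target, Socs2, had a log2 ratio of -0.28 (95% interval -0.44 to -0.12), the predicted direction but less than the 1.5-fold asked for, and this stays open. For interleukin 6 acting through STAT3, 9 other genes taken as targets, with enough reads, had a median of 0.12, with quartiles of 0.02 and 0.38. Bcl3 (-0.61) and Il1r1 (-0.06) went the predicted way. The median argues against a shared fall of these genes in replicate 2. Whether they follow STAT3 in this muscle was not tested, so interleukin 6 signalling stays open. Timp1 was in the list and had too few reads. Immediate-early genes had a median of -0.023 with members on both sides, Egr1 at -1.45 and Zfp36 at 0.56, so a stress response at dissection stays open.

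Of the 455 genes with a 2-fold difference in the first tables, 316 kept it in the second, Gm14440 among them on 0 and 0.9 reads, and 77 had under 1.5-fold in the second, 38 of them with no read there. The median relative posterior SD of the 77 was 80.3%, against 0% for the 316, which is consistent with reads assigned between near-identical copies. Gm10163 kept its ratio in the second tables (0 and 225.5 reads), although another gene is 100% identical over its 481 nt. It and its identical copies Gm10240 and Gm13370, pseudogenes close to Rpl21, summed to 1318 and 1595 reads, a log2 ratio of 0.32. No biological explanation was tested for these genes.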
